A study of Homo sapiens with 9 samples.

How the data were processed

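RNA was sequenced from primary cells of uterine leiomyoma, the benign smooth muscle tumour of the uterus also called a fibroid. Per the labels' protocols, the cells were transfected for 72 h with a control siRNA (siCtrl) or with 1 of 2 siRNAs against PGR, the gene of the progesterone receptor (siPGR-1 and siPGR-2). They were then stimulated for 24 h with R5020, a synthetic progesterone agonist, at 1e-07 M. Each of the 3 groups had 3 libraries, 9 in all. The replicate number is the PT number of the sample titles, read here as the donor of the cells. On that reading replicate 1 of siCtrl, siPGR-1 and siPGR-2 share a donor, and the replicates of a group are separate donors. The comparison of replicates below leaves this reading uncertain.

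The deposited values are read counts per gene, whole numbers that the authors had not normalized. Per the submitters' processing notes, STAR, HTSeq and DESeq2 were used with the genome build hg19. Their versions, the annotation and the strand setting of the counting are not given in the sources used here, so a gene and an antisense partner cannot be told apart and no coordinates are given. Each file held 56638 gene entries, of which 39969 had at least 1 count in any library and 33311 matched a table of gene symbols. It also held 5 HTSeq summary entries for reads not assigned to a gene. These took 33.6 to 46.2% of all entries' reads per library and stayed out of library sizes and tests. Reads aligned to more than 1 place were among them, so genes with near-identical copies are undercounted and uncertain. All 37 mitochondrial entries were 0 in all libraries, and the mitochondrial share could not serve as a measure of RNA quality.

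The counts assigned to genes ranged from 20660425 to 47616627 per library. Simulated counts with the real means, library sizes and spread tested what this depth and number of libraries could show. In them 200 genes were changed, all among genes expected at over 50 counts per library. With all siPGR libraries against siCtrl, the simulation recovered 31.3% of genes changed 1.5-fold, 89.6% of those changed 2-fold and 98.5% of those changed 4-fold. The 2-fold share was 74.6% for siPGR-1 against siCtrl, 70.2% for siPGR-2 against siCtrl and 67.2% for siPGR-2 against siPGR-1. The 1.5-fold shares of these comparisons were 7.46%, 13.4% and 8.96% in these simulations. Simulated libraries were independent, and in the siPGR comparison both siRNAs changed a gene by the same fold. The shares therefore do not cover genes with fewer counts, siRNAs that differ or libraries that depart together.

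Replicates were compared before averaging. No files held identical values. A chi-square test on genes with at least 20 counts over a pair of libraries gave a chi-square per degree of freedom of 3.38 to 9.57 between libraries of 1 group, except for siCtrl replicate 2 and siPGR-2 replicate 2, which reached 106 to 173 against their own groups. These 2 libraries also had the lowest RN7SL1 level, the RNA of the signal recognition particle, and the lowest share of reads aligned to more than 1 place. Against each other they were at 75.7. In contrast, siPGR-1 replicate 2 was at 3.38 against siPGR-1 replicate 1, but at 241 against siCtrl replicate 2 and 174 against siPGR-2 replicate 2. That the number stands for the donor therefore stays uncertain, as does the reading of a group's replicates as separate donors. If they are not, the standard deviations, standard errors and p-values below do not measure variation between donors. A block by replicate number may then also pair libraries that do not belong together. Both siCtrl replicate 2 and siPGR-2 replicate 2 stayed in every comparison, and each count was computed again without them. The libraries then left differ within a group by 3.38 to 9.57 only. Those fits rest on this small spread, and their counts are no independent repeat.

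Genes were tested with edgeR 4.0.16 in R 4.3.3, with TMM scaling, its filter on low counts (a minimum count of 10 and a minimum total of 15, which left 19735 genes) and the quasi-likelihood F-test. The siPGR comparison fitted the 6 siPGR libraries against the 3 siCtrl libraries. Each siRNA against siCtrl, and siPGR-2 against siPGR-1, were contrasts of 1 fit with 3 groups over all 9 libraries, which share 1 estimate of the spread. P-values were adjusted by Benjamini-Hochberg over all genes tested, with a threshold of 0.05. Levels of single genes are in CPM, the usual scaling of a count by the total of gene counts in its library. For named genes other than PGR, RN7SL1 and MALAT1 they were scaled by TMM. Errors of log2 fold changes are standard errors (SE) and errors of CPM are standard deviations (SD).

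No term for the replicate number was in these fits. The pairing by replicate number was checked through the deviations of each library from its group mean across genes. The 9 pairs of libraries with the same number from different groups had correlations of 0.13 to 0.68 (median 0.54), and the 18 pairs with different numbers had correlations of -0.53 to 0.32 (median -0.32). The pair at 0.68 was siCtrl replicate 2 and siPGR-2 replicate 2. Deviations cancel out within a group, so positive correlations for the same number draw those for different numbers to negative values. The 2 medians are therefore not separate evidence. Libraries of number 3 also had the fewest counts and the most reads aligned to more than 1 place (29.3 to 31.3%). The check therefore cannot tell a shared donor from shared technical features. The fit with the replicate number as a block is given beside a result where it changed a call or moved a count by more than 1.5 times.

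Before the data were examined, 30 gene lists, the rule for named genes and most of the alternative settings were written down. The rule took PGR, and among genes with a symbol, a mean of at least 50 counts, a passing test and 1 sign in all differences within a replicate number, the 10 with the largest rise and the 10 with the largest fall under siPGR. It took 5 in each direction for siPGR-2 against siPGR-1, and from each list the 4 tested members with the smallest p. The result of 1 such list member is not reported here. The lists were progestin-responsive genes, smooth muscle contractile genes, extracellular matrix, matrix proteases and inhibitors, TGF-beta, activin and BMP signalling, S phase, mitosis, the BCL2 family, p53 targets, interferon-stimulated genes, inflammatory cytokines and NF-kB targets, WNT signalling, steroid receptors and metabolism, the retinoid pathway, DNA methylation and demethylation, cholesterol synthesis and uptake, the unfolded protein and amino acid stress response, immediate early genes, growth factors and their receptors, hypoxia and glycolysis, nuclear-encoded oxidative phosphorylation, and siRNA machinery. Markers of endothelial cells, leukocytes, mast cells, epithelial cells, pericytes and fibroblasts, mitochondrial genes and ribosomal protein genes completed them. Each list's members were counted past the test over all genes and adjusted over the list alone. Lists with at least 5 tested members were also tested with camera (limma 3.58.1) at a preset correlation between genes of 0.01, adjusted over the lists, and again with the correlation estimated per list. Fry was an alternative.

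The other alternatives were a replicate block, DESeq2 size factors, no scaling beyond library size, DESeq2 1.42.0 with and without the block, limma-voom with the replicate number as a random effect, 1 factor estimated by sva 3.50.0, other filters on low counts, other sets of libraries in the fit, and leaving out each library or each replicate number. Chosen after seeing the data were the fits without siCtrl replicate 2 and siPGR-2 replicate 2, the fits with these 2 libraries as a factor, the list tests for each siRNA against siCtrl, and the simulation of unchanged groups with replicate effects. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.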

Results

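The series measured gene expression by RNA sequencing in primary human uterine leiomyoma cells after knockdown of PGR, which encodes the progesterone receptor. The question was which genes depend on this receptor in leiomyoma cells stimulated with a progesterone agonist. Cells received a control siRNA (siCtrl), siPGR-1 or siPGR-2, with 3 libraries per group whose numbers were read as donors. The reads counted to genes were 47616627, 26733401 and 21674374 in siCtrl replicates 1 to 3, 38680178, 38820284 and 20660425 in siPGR-1, and 39279712, 38341881 and 22614358 in siPGR-2.

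PGR itself was lower in all siPGR libraries than in any siCtrl library. It had 16009, 13083 and 7408 counts in siCtrl replicates 1 to 3, 807, 717 and 402 counts in siPGR-1, and 699, 1940 and 401 counts in siPGR-2. The level was 389 ± 86.9 CPM in siCtrl, 19.6 ± 1.20 CPM in siPGR-1 and 28.7 ± 19.0 CPM in siPGR-2 (SD, n = 3 each). The 6 siPGR libraries together were 17.3-fold lower than siCtrl (log2 fold change -4.11, SE 0.34, edgeR adjusted p = 2.66e-05, lower in 6 of 6). The fold was 22.6 for siPGR-1 (log2 -4.50, SE 0.42, adjusted p = 8.56e-05) and 13.96 for siPGR-2 (log2 -3.80, SE 0.40, adjusted p = 0.000325), each lower in 3 of 3. Between siPGR-2 and siPGR-1 the PGR difference of 0.70 (SE 0.37) did not pass the edgeR test (adjusted p = 0.385). Without siCtrl replicate 2 and siPGR-2 replicate 2, called the 2 set-apart libraries from here on, that difference was -0.033 (adjusted p = 0.714).

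**Figure D1:**
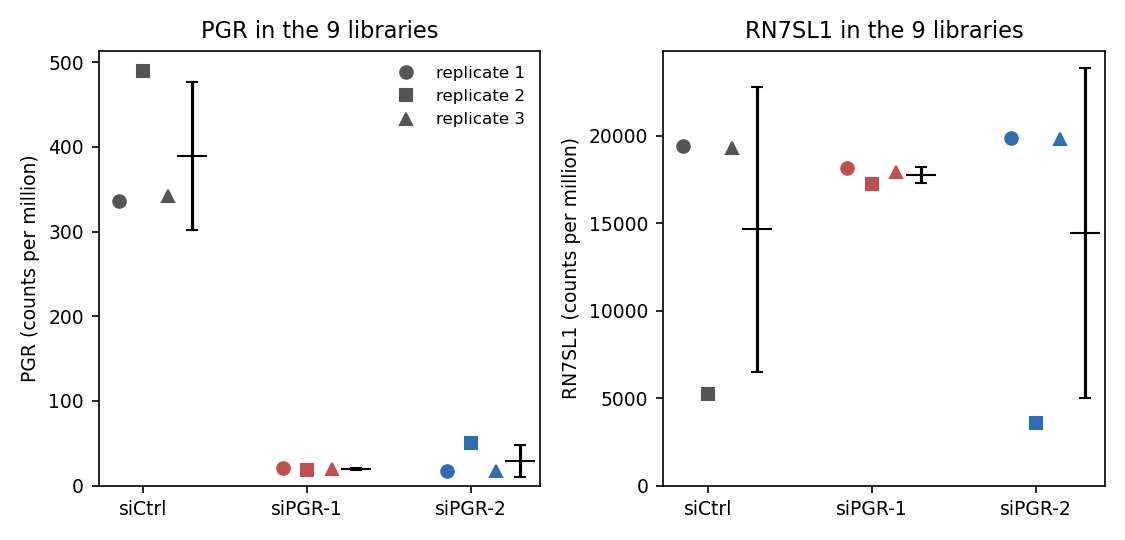
PGR (left) and the signal recognition particle RNA RN7SL1 (right) in CPM, 1 point per library, with the group mean and SD as bars (n = 3). PGR lay between 336 and 489 in siCtrl and at or under 50.6 in the siPGR libraries, while RN7SL1 was 5248 in siCtrl replicate 2 and 3573 in siPGR-2 replicate 2, against 17229 to 19883 in the other 7 libraries.

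Besides PGR, the largest falls over the 6 siPGR libraries together were in IGF1, PI15 and DIO2, and the largest rises in SPRR2G, IL36RN and IL36B. IGF1, the insulin-like growth factor, fell 22.6-fold (log2 -4.50, SE 0.67), from 176 ± 91.5 CPM in siCtrl to 7.71 ± 9.10 CPM in the 6 siPGR libraries. The peptidase inhibitor PI15 fell 19.7-fold (log2 -4.30, SE 0.45), DIO2, the deiodinase that activates thyroid hormone, 13.97-fold (log2 -3.80, SE 0.27), and MASP1, a serine protease of the complement lectin pathway, 12.2-fold. At the other end, SPRR2G, a small proline-rich protein of the cornified envelope, rose 23.4-fold (log2 4.55, SE 0.66), IL36RN, an interleukin receptor antagonist, 19.5-fold (log2 4.29, SE 0.90), and the cytokine IL36B 13.02-fold (log2 3.70, SE 0.70). Each moved in 1 direction in all 6 differences within a replicate number, with edgeR adjusted p-values of 0.00740 or less. The rule for named genes required this sign and a passing test, so neither is further support. The 6 differences also share the 3 siCtrl libraries. By siRNA, SPRR2G rose 32.2-fold with siPGR-1 and 14.5-fold with siPGR-2, IL36RN 33.2-fold and 5.75-fold, and IL36B 20.3-fold and 5.67-fold, while with siPGR-2 KRTAP2-3 rose 9.97-fold, KSR2 8.40-fold and FGF5 7.33-fold. Between the siRNAs IL36RN and IL36B differed (adjusted p = 0.00967 and 0.0350), and SPRR2G did not pass (adjusted p = 0.167).

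The rule for named genes was met by 1314 genes that rose and 1751 that fell. The remaining largest rises were KSR2, a scaffold of the Ras pathway (11.8-fold), the integrin subunit ITGAX (10.5-fold), PRR9 (10.1-fold), KRTAP2-3 (9.30-fold), the growth factor FGF5 (7.05-fold), the potassium channel KCNA3 (6.96-fold) and the organic anion transporter SLCO2B1 (6.66-fold). The remaining largest falls were ACTBL2 (11.96-fold), ZCCHC12 (11.7-fold), SERTM1 (11.3-fold), MYOC, which encodes myocilin (11.2-fold), and CADPS, a factor of vesicle release (11.1-fold). SPRR2G, KRTAP2-3 and ACTBL2 belong to families with near-identical members, which makes their levels uncertain. In all, 3583 of 19735 genes passed the edgeR test, 1569 higher and 2014 lower in siPGR, and 1237 of them by at least 2-fold (560 higher, 677 lower). With library size only, 2256 genes were higher and 1552 lower, and the median of all genes moved to 0.12 from 0.01, so directions are relative to the TMM scaling. The count was 2213 without siCtrl replicate 1, 2168 without siCtrl replicate 3 and 6319 without siCtrl replicate 2 and siPGR-2 replicate 2, where 3473 of the 3583 genes passed again. The libraries in that last fit differ little within a group, so passing again there is no independent repeat. PRR9 was 15.3-fold higher with siPGR-1 (adjusted p = 0.00623), and with siPGR-2 its fold of 4.802 did not pass (adjusted p = 0.0801), while the difference between the siRNAs did not pass either (adjusted p = 0.270). PRR9 and SLCO2B1 lost their call without siCtrl replicate 1 or siCtrl replicate 3 (highest adjusted p = 0.0578 and 0.0858).

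**Figure D2:**
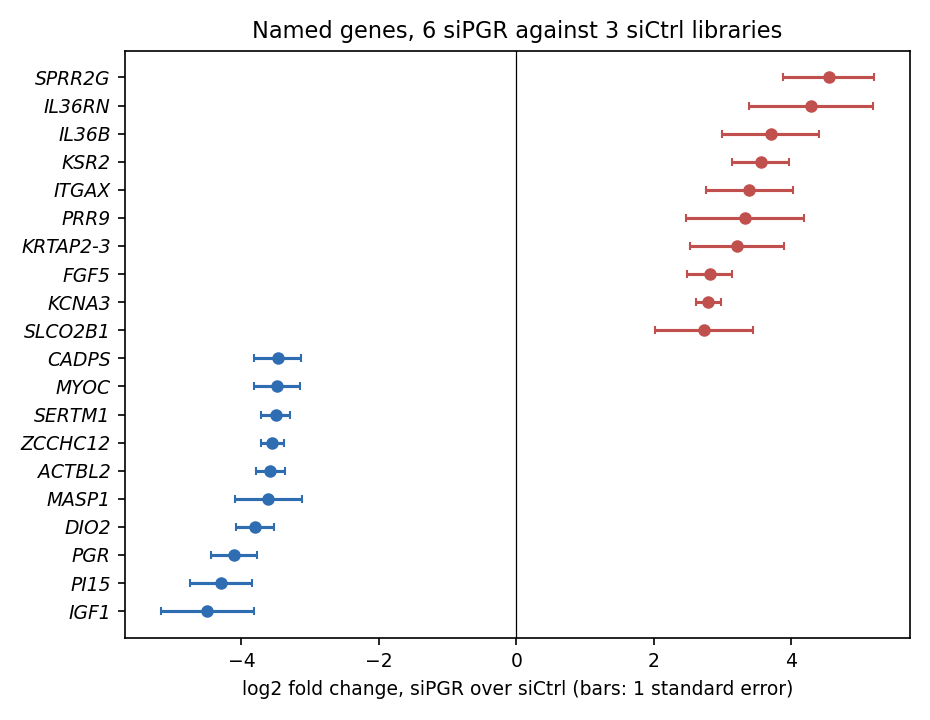
The 10 genes with the largest rise and the 10 with the largest fall by the fixed rule. Points are log2 fold changes of the 6 siPGR libraries over the 3 siCtrl libraries and bars are 1 standard error, running from IGF1 at -4.50 to SPRR2G at 4.55.

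Genes of cell division rose together. All 30 mitosis genes were higher in siPGR (30 also when adjusted over the list alone), with a median log2 fold change of 1.53. MKI67, the proliferation marker, rose 4.01-fold (log2 2.00, SE 0.14), CCNA2, the cyclin of S phase and mitosis, 3.73-fold, the checkpoint kinase BUB1B 3.63-fold and the spindle protein TPX2 3.22-fold, each in 6 of 6 libraries. Of 26 S phase genes 23 rose, 0 fell and 3 did not pass, while adjusted over the list alone 23 rose and 1 fell (median 1.19). The ribonucleotide reductase subunit RRM2 rose 4.37-fold (log2 2.13, SE 0.13), RRM1 2.21-fold and the thymidylate synthase TYMS 3.10-fold. Camera placed both lists above other genes (adjusted p = 3.72e-49 for mitosis and 7.84e-28 for S phase). The calls were lost with an estimated correlation, with adjusted p = 0.0611 with an estimated correlation for mitosis and 0.103 for S phase. With each siRNA against siCtrl on its own, the adjusted p with an estimated correlation was 0.0411 (siPGR-1) and 0.0159 (siPGR-2) for mitosis, and 0.110 and 0.0352 for S phase, and none of these passed with the block added. In the same libraries 7 of 12 endothelial markers were lower (median -0.54).

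Among 19 genes of DNA methylation and demethylation, 4 rose, 3 fell and 12 did not pass (4 higher and 5 lower adjusted over the list alone, 5 higher and 8 lower without the 2 set-apart libraries), and camera did not place the list apart (adjusted p = 0.497). The risers were UHRF1 (3.25-fold), the maintenance methyltransferase DNMT1 (1.85-fold, log2 0.89, SE 0.10), the chromatin remodeller HELLS (2.23-fold) and the cytidine deaminase APOBEC3B (2.78-fold). UHRF1 is also in the S phase list.

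Of 34 progestin-responsive genes, 13 fell under siPGR, 3 rose and 18 did not pass, against 18 lower and 5 higher adjusted over the list alone (median -0.47). PRL, the prolactin gene, fell 10.9-fold (log2 -3.44, SE 0.28), the kinase PDK4 5.24-fold (log2 -2.39, SE 0.25) and the amino acid transporter SLC7A8 1.87-fold, besides DIO2. The camera test gave an adjusted p = 3.31e-06, and adjusted p = 0.111 with an estimated correlation (0.00664 with siPGR-1 and 0.0159 with siPGR-2 on its own, 0.0812 and 0.103 with the block added). Of 31 genes of steroid receptors and steroid metabolism, 7 fell, 2 rose and 22 did not pass (9 lower and 2 higher adjusted over the list alone, 13 and 2 without the 2 set-apart libraries, median -0.19). GREB1, a hormone-induced cofactor of the estrogen receptor, fell 8.32-fold (log2 -3.06, SE 0.14), STAR, the carrier of cholesterol into mitochondria, 6.47-fold, HSD11B1, which makes active cortisol, 4.14-fold, and the estrogen receptor gene ESR1 2.88-fold (log2 -1.53, SE 0.13), each in 6 of 6 libraries. By camera, the adjusted p was 1.91e-05, and this list alone kept its call in the siPGR comparison (adjusted p = 0.0331 with an estimated correlation, 0.130 with the block added and 0.156 without the 2 set-apart libraries). Of 21 retinoid pathway genes, 7 fell, 2 rose and 12 did not pass (8 lower and 2 higher adjusted over the list alone). CRABP2, a retinoic acid binding protein, fell 4.43-fold and the retinaldehyde dehydrogenases ALDH1A1 and ALDH1A2 fell 3.17-fold and 2.17-fold, while STRA6, the retinol uptake receptor, rose 3.00-fold. For the list, camera's adjusted p was 0.00393, and adjusted p = 0.305 with an estimated correlation. Beside these lists too, 7 of 12 endothelial markers were lower.

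Of 39 structural genes of the extracellular matrix, 14 fell under siPGR, 4 rose and 21 did not pass (20 lower and 4 higher adjusted over the list alone, 26 and 7 without the 2 set-apart libraries, median -0.61). THBS2, a matricellular thrombospondin, fell 2.88-fold from 2136 ± 60.7 CPM in siCtrl (log2 -1.53, SE 0.13), the dermatopontin gene DPT 2.97-fold, the collagen gene COL8A1 2.80-fold and elastin, ELN, 1.98-fold. The adjusted p of camera was 6.03e-06, and adjusted p = 0.632 with an estimated correlation. Of 27 matrix proteases and inhibitors, 9 fell, 5 rose and 13 did not pass (9 lower and 7 higher adjusted over the list alone). The inhibitors SERPINE2 and TIMP3 fell 6.07-fold and 5.54-fold, and the aggrecan-cleaving proteases ADAMTS4 and ADAMTS5 fell 3.42-fold and 3.37-fold. Camera gave an adjusted p = 0.00194, and adjusted p = 0.0644 with an estimated correlation. In these libraries 7 of 12 endothelial markers were lower as well (median -0.54).

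Signalling genes fell more often than they rose. Of 33 genes of TGF-beta, activin and BMP signalling, 13 fell, 1 rose and 19 did not pass, with equal counts adjusted over the list alone. TGFB3, a TGF-beta ligand, fell 3.70-fold (log2 -1.89, SE 0.21), the pseudoreceptor BAMBI 3.69-fold, the co-receptor TGFBR3 2.89-fold and PMEPA1, an inhibitor of this pathway, 1.82-fold. The camera test gave an adjusted p = 2.13e-06, and adjusted p = 0.154 with an estimated correlation (0.00664 with siPGR-1 and 0.0159 with siPGR-2 on its own, 0.0524 and 0.0811 with the block added). Of 29 WNT genes, 12 fell, 2 rose and 15 did not pass (13 lower and 2 higher adjusted over the list alone). The secreted WISP1 fell 3.17-fold, the transcription factor TCF7L2 2.26-fold, the receptor FZD1 1.60-fold and the WNT enhancer RSPO3 1.57-fold. By camera, the adjusted p was 0.000307, and adjusted p = 0.314 with an estimated correlation. Of 35 growth factors and receptors, 12 fell, 6 rose and 17 did not pass (16 lower and 6 higher adjusted over the list alone, 21 and 6 without the 2 set-apart libraries). HGF, the hepatocyte growth factor, fell 4.37-fold (log2 -2.13, SE 0.17) while its receptor gene MET rose 2.89-fold (log2 1.53, SE 0.13), IGFBP5 fell 2.34-fold from 8747 ± 789 CPM, and FGF5 rose. For the list, camera's adjusted p was 0.00348, and adjusted p = 0.338 with an estimated correlation. The 7 lower endothelial markers of 12 stand beside the signalling lists as well.

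Inflammatory and hypoxia genes also fell more often than they rose. Of 29 inflammatory cytokines and NF-kB targets, 10 fell, 2 rose and 17 did not pass (11 lower and 2 higher adjusted over the list alone). The chemokine CXCL5 fell 8.34-fold (log2 -3.06, SE 0.23), the cyclooxygenase PTGS2 5.33-fold (log2 -2.41, SE 0.21), IL11 3.10-fold and IL33 2.12-fold. The adjusted p of camera was 0.000154, and adjusted p = 0.273 with an estimated correlation (0.0460 without the 2 set-apart libraries). Of 28 hypoxia and glycolysis genes, 11 fell, 1 rose and 16 did not pass (12 lower and 1 higher adjusted over the list alone). The carbonic anhydrase CA9 fell 4.88-fold, the prolyl hydroxylase EGLN3 3.43-fold and the lactate dehydrogenase LDHA 2.15-fold, while the mitophagy receptor BNIP3L rose 1.62-fold. Camera gave an adjusted p = 2.46e-05, and adjusted p = 0.103 with an estimated correlation. Of 26 immediate early genes, 6 fell, 5 rose and 15 did not pass, with equal counts adjusted over the list alone (11 and 8 without the 2 set-apart libraries), and camera did not pass (adjusted p = 0.125). The orphan nuclear receptors NR4A3, NR4A2 and NR4A1 fell 5.80-fold, 5.44-fold and 1.84-fold, and FOS fell 2.20-fold. The endothelial markers, 7 of 12 lower, moved in the same libraries.

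The smooth muscle contractile genes did not pass in the siPGR comparison. edgeR called 0 of 29 over all genes and 0 adjusted over the list alone (median -0.26, 6 at an unadjusted p under 0.05, and 2 higher and 1 lower without the 2 set-apart libraries), and camera gave an adjusted p = 0.125. DESeq2 called 1 higher and 1 lower, limma-voom 0, and a fit that kept both siRNAs as separate groups called 1 higher and 11 lower for their mean. ACTA2, the smooth muscle actin, had a log2 fold change of -0.90 (SE 0.34, adjusted p = 0.0972), ACTG2 -0.70 (SE 0.27), TPM2 -0.49 (SE 0.20) and CSRP1 0.55 (SE 0.21). This comparison holds 2 siRNAs that differed in this list, as given for siPGR-2 against siPGR-1.

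Markers of other cell types were tested beside these lists. Of 12 endothelial markers, 7 were lower in siPGR, 0 higher and 5 not passing, with 7 lower adjusted over the list alone (median -0.54). EGFL7 was 1.78-fold lower, the VEGF receptor gene KDR 1.55-fold, the cadherin gene CDH5 1.98-fold and EMCN 1.43-fold. The camera test gave an adjusted p = 0.000307, and adjusted p = 0.448 with an estimated correlation. EMCN lost its call without siCtrl replicate 1 or siCtrl replicate 3 (highest adjusted p = 0.0622). Of 10 pericyte markers, 3 were lower and 7 did not pass (5 lower and 1 higher adjusted over the list alone, 5 lower with the replicate block, 5 lower and 2 higher without the 2 set-apart libraries), with RGS5 1.69-fold, KCNJ8 1.79-fold and the channel subunit ABCC9 1.62-fold lower, and NOTCH3 at -0.64 (SE 0.21, adjusted p = 0.0547, and 0.0312 with the replicate block). The pericyte list had a camera adjusted p = 0.0507, which was 0.0295 with the replicate block (adjusted p = 0.226 with the block and an estimated correlation). The call of ABCC9 was lost in 6 of 9 fits that left out 1 library, siCtrl replicate 1, siCtrl replicate 2, siPGR-2 replicate 3 or any siPGR-1 library (highest adjusted p = 0.112). Of 12 fibroblast markers, 6 fell, 2 rose and 4 did not pass, with equal counts adjusted over the list alone and a camera adjusted p = 0.728. The peptidases DPP4 and MME rose 4.19-fold and 4.497-fold, while CD34 fell 2.85-fold and COL14A1 4.38-fold. COL14A1 lost its call without siCtrl replicate 2 (adjusted p = 0.0560). edgeR called 0 of 9 leukocyte and 0 of 8 epithelial markers, over all genes and adjusted over the list alone (0 and 2 at an unadjusted p under 0.05, camera adjusted p = 0.745 and 0.996). DESeq2 called 0 leukocyte markers and 1 epithelial marker in each direction, limma-voom 0 and 1, and the replicate block gave 1 lower epithelial marker. For the epithelial list the median was -0.03 and camera's direction was up. The 1 mast cell marker tested did not pass.

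**Figure D3:**
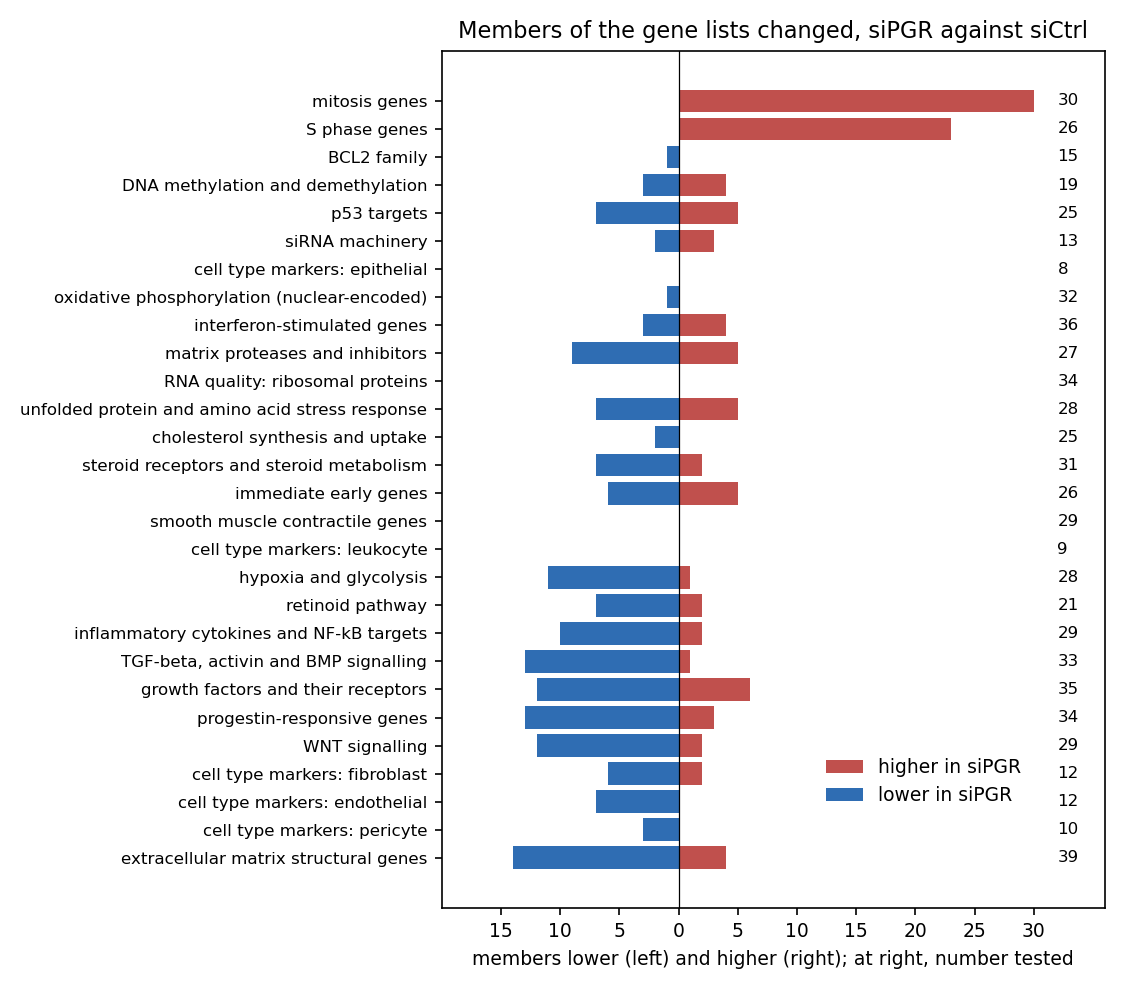
Members of each gene list past the edgeR test in siPGR against siCtrl, counted to the right where higher and to the left where lower, with the number tested at the right edge. The 30 mitosis genes and 23 of 26 S phase genes lie to the right, and the matrix list has 14 members to the left and 4 to the right.

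Each siRNA was also compared with siCtrl on its own. With siPGR-1, 4817 of 19735 genes passed the edgeR test, 1924 higher and 2893 lower. With siPGR-2, 2750 genes passed, 1324 higher and 1426 lower. All 30 mitosis genes were higher under each siRNA (median 1.38 for siPGR-1 and 1.69 for siPGR-2). With an estimated correlation, camera kept 7 lists for siPGR-1 (mitosis, progestin-responsive, TGF-beta, WNT, steroid, growth factor and hypoxia) and 6 for siPGR-2 (mitosis, S phase, progestin-responsive, TGF-beta, steroid and hypoxia), a test chosen after seeing the data. None of these kept its call with the block added (lowest adjusted p = 0.0524 and 0.0811) or without the 2 set-apart libraries (lowest 0.177 and 0.0557). By camera, endothelial markers were lower with siPGR-1 and siPGR-2 (adjusted p = 0.00419 and 0.00262, but 0.533 and 0.629 with an estimated correlation). Both siRNAs called 2317 genes, 2314 of them in the same direction. Under siPGR-1, library size only turned the split to 3363 higher and 1875 lower, with the median of all genes at 0.20. The siPGR-1 count was 3120 without siPGR-1 replicate 1 and 9984 without siCtrl replicate 2 and siPGR-2 replicate 2. The siPGR-2 count was 1771 without siCtrl replicate 1, 1800 without siCtrl replicate 3, 1718 without siPGR-2 replicate 1, 1690 without siPGR-2 replicate 3, 4307 without siPGR-2 replicate 2 and 7784 without siCtrl replicate 2 and siPGR-2 replicate 2.

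The fold changes of both siRNAs were correlated across genes, which are not independent replicates (Pearson r = 0.789, Spearman rho = 0.723, covariance 0.329). Groups simulated as unchanged against the same controls gave a mean r of 0.516 (0.477 to 0.544 over 20 simulations) and a covariance of 0.0971, which leaves a difference in covariance of 0.232. These simulated libraries were independent. Groups simulated with the fitted effects of the replicate number, where libraries of 1 number deviated together (median correlation 0.543), gave a mean r of 0.528 and a covariance of 0.0525, which leaves 0.276. Every simulated group had the same replicate effects, which largely cancel in differences between groups. That simulation therefore could not show agreement that comes from replicate effects, and its difference is no further support. It also does not cover libraries that depart in some groups only, as the 2 set-apart libraries do. The signs matched for 77.9% of genes, against 67.0% in the simulations. In the upward direction 1034 genes were shared where independent lists would share 129, and in the downward direction 1280 where they would share 209. The independent simulated groups shared 0.05 in each direction on average, but they hold almost no calls and do not measure how many shared calls the controls add. With control libraries of different replicate numbers, so that no control was shared, the mean r over 6 choices was 0.545 (0.494 to 0.600) and the mean covariance 0.266. The 3 control libraries cannot be split so that each part keeps 2, so part of the excess in shared calls may come from the shared controls.

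The contrast of siPGR-2 with siPGR-1 asks where 2 siRNAs against 1 gene differed. Of 29 smooth muscle contractile genes, 14 were higher in siPGR-2, 0 lower and 15 not passing, with 21 higher adjusted over the list alone and 27 without the 2 set-apart libraries (median 0.61). CNN1, the calponin gene, was 2.27-fold higher (log2 1.18, SE 0.11), at 144 CPM in siPGR-1 and 328 CPM in siPGR-2 against 394 ± 33.5 CPM in siCtrl. PLN, which regulates the calcium pump, was 2.59-fold higher (log2 1.37, SE 0.13), ACTA2 2.39-fold and MYOCD, the coactivator of smooth muscle genes, 2.08-fold, each in 3 of 3 differences within a replicate number. By camera, the adjusted p was 1.60e-25, and adjusted p = 0.0191 with an estimated correlation (0.0451 with the block added, 0.0339 without the 2 set-apart libraries). Against siCtrl, 16 contractile genes were lower with siPGR-1 (20 adjusted over the list alone, camera adjusted p = 1.13e-07, and 0.075 with an estimated correlation), and with siPGR-2 2 were higher and 0 lower. Without the 2 set-apart libraries these counts were 3 higher and 21 lower with siPGR-1, and 11 higher and 10 lower with siPGR-2. Markers of 3 other cell types also changed against siCtrl. With siPGR-1, 6 of 10 pericyte, 7 of 12 fibroblast and 5 of 12 endothelial markers were lower, and 1, 2 and 0 higher. With siPGR-2 2, 2 and 3 were lower and 0, 2 and 0 higher. Adjusted over the list alone, 9 endothelial markers were lower with siPGR-1 and 8 with siPGR-2. Between the siRNAs 0 of 12 endothelial markers passed (median 0.09, camera adjusted p = 0.550, 5 lower without the 2 set-apart libraries). Of 10 pericyte markers 1 was higher and 0 lower in siPGR-2 (median 0.24, camera adjusted p = 0.320). The fibroblast median between the siRNAs was 0.68, with 0 higher and 1 lower (camera adjusted p = 0.0299, and 0.616 with an estimated correlation). Without the 2 set-apart libraries that median was 0.22, with 6 higher and 3 lower. In siPGR-1, HTSeq assigned 13.9 to 15.5% of reads to no counted feature of the annotation, against 8.002 to 9.76% in replicates 1 and 3 of siCtrl and siPGR-2. The share was 17.3% in siCtrl replicate 2 and 17.5% in siPGR-2 replicate 2.

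**Figure D4:**
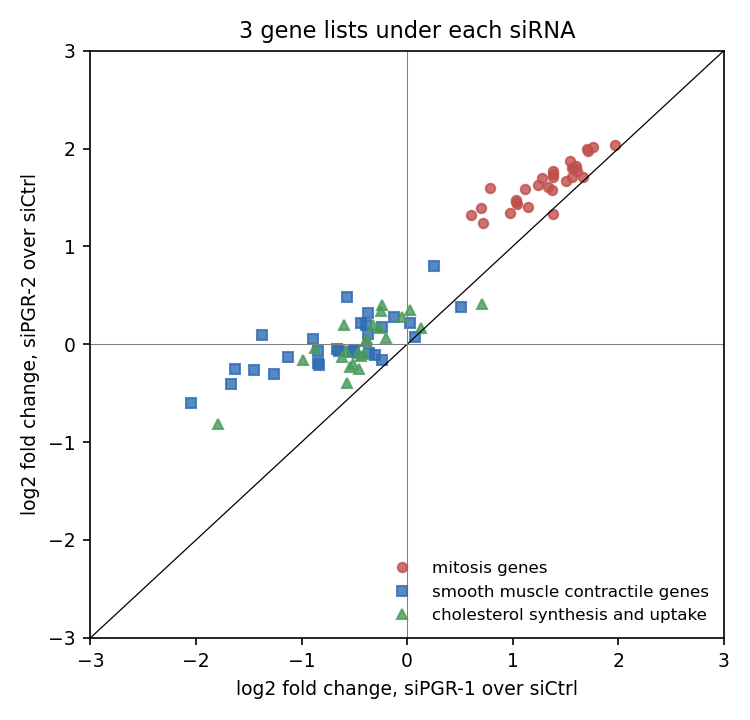
Log2 fold changes of the mitosis, contractile and cholesterol genes with siPGR-1 (horizontal) and siPGR-2 (vertical) over siCtrl, 1 point per gene, with the line of equal change. All 30 mitosis genes are above 0 on both axes, and contractile genes lie mainly above the line, with a median difference of 0.61 between the siRNAs.

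In all, 753 genes passed the edgeR test between the siRNAs, 563 higher and 190 lower in siPGR-2, and the replicate block gave 1261 (864 higher, 397 lower), 746 of them among the 753. With library size only the split was 178 higher and 313 lower, and the median of all genes was at -0.14. By the rule for named genes, the largest differences upward in siPGR-2 were KCND2, a potassium channel (3.74-fold), the tetraspanin TSPAN2 (3.50-fold), OXTR, the oxytocin receptor (3.42-fold, log2 1.77, SE 0.28), KIAA1199 (3.22-fold) and TC2N (3.05-fold). KIAA1199 was at 53.9 CPM in siPGR-2 replicate 2, against 8.54 to 18.0 CPM in the other siPGR libraries. Its log2 difference of 1.69 became 0.89 without the 2 set-apart libraries, and its call was lost in 6 of 9 fits without 1 library. The largest downward were IGFN1 (6.30-fold), IL36RN (5.78-fold), the lipase-related PNLIPRP3 (4.72-fold), SLCO2B1 (4.29-fold) and ITGAX (3.83-fold). IL36RN, SLCO2B1 and ITGAX were higher than siCtrl in the siPGR comparison, with levels of 88.3, 6.26 and 29.9 CPM in siPGR-1 and 15.3, 1.46 and 7.80 CPM in siPGR-2. The count fell to 13, 22 and 46 without siPGR-1 replicate 1, 2 or 3, to 217 and 254 without siPGR-2 replicate 1 or 3, and to 322 and 423 without siCtrl replicate 1 or 3. It was 1691 without siCtrl replicate 2, 1228 without siPGR-2 replicate 2 and 6349 without both, where all 753 passed again. Without both, the libraries left differ little within a group, so this is no independent repeat. Of 39 genes named for this contrast, ITGAX, CNN1 and PLN kept their call whichever single library was left out, and none kept it in a fit of only the 6 siPGR libraries with the replicate block, which called 0 genes (3127 at an unadjusted p under 0.05, and 1507 by DESeq2 with the block on all 9 libraries).

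Other lists had fewer members past the test between the siRNAs. Of 34 progestin-responsive genes 6 were higher in siPGR-2 and 0 lower (14 higher and 3 lower adjusted over the list alone, 15 and 4 without the 2 set-apart libraries), with the monoamine oxidase genes MAOA 1.58-fold and MAOB 2.10-fold and the transcription factor CEBPD 2.09-fold higher (camera adjusted p = 0.000220, and adjusted p = 0.0263 with an estimated correlation, 0.189 with the block added). Of 33 TGF-beta genes 4 were higher (10 adjusted over the list alone, 10 with the replicate block, 21 without the 2 set-apart libraries and 2 lower), with INHBA, an activin subunit, 1.70-fold and the BMP antagonist GREM1 1.73-fold higher (camera adjusted p = 5.72e-06, and adjusted p = 0.0191 with an estimated correlation). Of 35 growth factor genes 3 were higher (7 adjusted over the list alone, 6 with the block, 17 without the 2 set-apart libraries and 4 lower), with the receptor FGFR2 2.91-fold and IGFBP3 1.93-fold higher (camera adjusted p = 6.17e-05, and adjusted p = 0.0228 with an estimated correlation). These were, with the contractile list, the 4 lists whose call was kept with an estimated correlation, and the block then ended the call of the progestin-responsive list. Without the 2 set-apart libraries the calls of the progestin-responsive, TGF-beta and growth factor lists were lost with an estimated correlation (adjusted p = 0.187 each). Of 25 cholesterol genes 5 were higher (16 adjusted over the list alone, 8 with the block, 17 without the 2 set-apart libraries, median 0.42), among them ACAT2 1.503-fold, IDI1 1.40-fold and DHCR7 1.97-fold (camera adjusted p = 1.17e-09, and adjusted p = 0.104 with an estimated correlation). Against siCtrl 10 cholesterol genes were lower with siPGR-1 (15 adjusted over the list alone), and with siPGR-2 1 was higher and 1 lower, against 2 higher and 15 lower with siPGR-1 and 7 higher and 10 lower with siPGR-2 without the 2 set-apart libraries. Of 39 matrix genes THBS1 was higher, 2.00-fold (10 genes adjusted over the list alone, 12 with the block, 26 and 2 lower without the 2 set-apart libraries, camera adjusted p = 3.44e-10, and adjusted p = 0.564 with an estimated correlation). The share of reads in no counted feature in siPGR-1 stands beside these lists too.

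Of 36 interferon-stimulated genes, 4 were lower in siPGR-2 than in siPGR-1, 0 higher and 32 not passing (6 lower adjusted over the list alone, median -0.02), with the antiviral RSAD2 2.60-fold (log2 -1.38, SE 0.16), OASL 2.39-fold, CMPK2 1.81-fold and IRF7 1.46-fold lower. For the list, camera's adjusted p was 0.0214, and adjusted p = 0.729 with an estimated correlation. Without the 2 set-apart libraries 22 were lower and 0 higher (median -0.39, camera adjusted p = 2.02e-10, and adjusted p = 0.0339 with an estimated correlation). Of 30 mitosis genes 4 were higher in siPGR-2 and 26 did not pass, and of 26 S phase genes 4 were higher and 22 did not pass (4 and 5 higher adjusted over the list alone, 24 and 21 higher without the 2 set-apart libraries). Among them were KIF23 1.61-fold, AURKA 1.65-fold, MCM6 1.45-fold and CDC6 1.65-fold higher. Camera adjusted p-values were 6.42e-07 and 5.03e-05, and adjusted p = 0.503 and 0.572 with an estimated correlation (0.160 and 0.142 without the 2 set-apart libraries). The remaining calls of camera were WNT genes up (adjusted p = 0.000199, and adjusted p = 0.104 with an estimated correlation), retinoid genes up (0.00974 and adjusted p = 0.228 with an estimated correlation), hypoxia genes up (0.0212 and adjusted p = 0.295 with an estimated correlation), fibroblast markers up (0.0299 and adjusted p = 0.616 with an estimated correlation) and BCL2 genes down (0.0314 and adjusted p = 0.616 with an estimated correlation). Without the 2 set-apart libraries the hypoxia and BCL2 calls were lost (adjusted p = 0.271 and 0.592), and ribosomal protein genes (0.00166) and oxidative phosphorylation genes (0.0253) were called up, both with adjusted p = 0.690 with an estimated correlation. Single members of other lists also differed, with the cystine transporter SLC7A11 1.95-fold and the collagenase MMP1 1.45-fold lower in siPGR-2, and the glycolytic PGK1 1.497-fold and the amino acid transporter SLC7A5 1.72-fold higher.

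3 genes were called in opposite directions against siCtrl. MYOCD had a log2 fold change of -0.57 with siPGR-1 (edgeR adjusted p = 0.00426) and 0.48 with siPGR-2 (adjusted p = 0.0160). CCNG1, a p53-induced cyclin, had -0.32 (adjusted p = 0.0376) and 0.53 (adjusted p = 0.00593), and the transglutaminase TGM2 -0.31 (adjusted p = 0.0474) and 0.36 (adjusted p = 0.0407). The siRNAs differed from each other in all 3 genes, by 1.06, 0.85 and 0.67 (adjusted p = 0.00426, 0.00559 and 0.00983). Leaving out 1 library ended the siPGR-1 calls of CCNG1 and TGM2 in 8 of 9 fits, all but the one without siPGR-2 replicate 2 (highest adjusted p = 0.171 and 0.199). It ended the siPGR-2 call of TGM2 in 7 fits, all but those without siCtrl replicate 2 or siPGR-2 replicate 2 (highest adjusted p = 0.154), and that of MYOCD without siCtrl replicate 1, siCtrl replicate 3 or siPGR-2 replicate 3 (highest adjusted p = 0.0694). A fit of only the 6 libraries compared also ended the siPGR-2 calls of MYOCD (adjusted p = 0.0753) and TGM2, and the siPGR-1 calls of CCNG1 and TGM2 were lost in 5 and 6 of 11 other planned settings (highest adjusted p = 0.380 and 0.376). A further 244 genes were called by both siRNAs in the same direction and differed between them.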

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

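The test of the PGR left was chosen after its result had been seen. Dixon's test for a far value among the 6 siPGR libraries was run on 33 measures, and 8 exceeded its 95% critical value, where chance would give 1.65. All 8 lay in siPGR-2 replicate 2. Its RN7SL1 level was 3573 CPM against 17229 to 19883 CPM in the other siPGR libraries, its MALAT1 level, a nuclear noncoding RNA, was 26544 CPM against 9104 to 13322, and its 10 highest genes took 12.8% of counts against 10.2 to 10.98%. PGR was at 50.6 CPM against 17.7 to 20.9, IGF1 at 26.1 against 2.69 to 5.75, PI15 at 57.9 against 11.8 to 17.4, DIO2 at 19.3 against 7.34 to 11.5 and KIAA1199 at 53.9 against 8.54 to 18.0.

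The 2 libraries set apart were siCtrl replicate 2 and siPGR-2 replicate 2, which departed from their groups in similar genes (the log2 differences of both correlated at 0.681 across genes). The other library of that number, siPGR-1 replicate 2, had an RN7SL1 level of 17229 CPM. GC content and transcript length could be measured for 83.6% of tested genes, and the larger Spearman correlation with the siCtrl differences was 0.114 (length), against -0.252 (GC content) and 0.162 (length) for siPGR-2, too weak or too unequal to decide for or against such a bias. A different share of RNA from other cells stays open too, since the endothelial median was 0.41 in siCtrl and 0.55 in siPGR-2, pericyte 0.34 and 0.36, leukocyte -0.81 and 0.41, and epithelial 0.18 and -0.39. No library batch is named in the labels, and no biological explanation was tested.

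The siRNAs differed in MYOCD by 1.06, in CCNG1 by 0.85 and in TGM2 by 0.67 on the log2 scale, by a test of the difference itself, with opposite signs against siCtrl. For the 753 genes called between the siRNAs, 2 explanations were examined. The values on genomic DNA argue against it for the 190 genes lower in siPGR-2 only, and genes higher in siPGR-2 were not covered. Those on PGR cover only its RNA, without the 2 libraries set apart. The mean level per gene of 402 olfactory receptor genes, which stand for reads from genomic DNA, was 0.0369 CPM in siPGR-1 and 0.0275 CPM in siPGR-2 replicates 1 and 3, and the siPGR-1 value was 1.26% of the median gap of the 190 genes lower in siPGR-2 (2.93 CPM). For a different amount of PGR RNA left, the PGR difference was -0.033 (95% interval -0.16 to 0.10) without the 2 libraries set apart. That fit leaves out siPGR-2 replicate 2, the siPGR library with the most PGR (50.6 CPM). That interval rests on siPGR-2 replicates 1 and 3, which differ little. Over all 9 libraries the difference was 0.70 (SE 0.37, edgeR adjusted p = 0.385). With 1 factor estimated by sva it was 0.51 and passed (edgeR adjusted p = 0.0388). The near-equal PGR RNA therefore covers siPGR-2 replicates 1 and 3 only, and over all 9 libraries this explanation stays undecided. Receptor protein was not measured here. An effect of 1 siRNA on other transcripts, and unspliced RNA behind the reads in no counted feature in siPGR-1, remain candidate explanations that were not tested.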

How the results depend on the processing

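The fits without siCtrl replicate 2 and siPGR-2 replicate 2 and those with these 2 libraries as a factor were chosen after seeing the data. PGR fell past the threshold under siPGR and under each siRNA in every setting, with ranges of -4.49 to -3.91, -4.59 to -4.20 and -4.48 to -3.56 when libraries were left out. The PGR difference between the siRNAs was 0.51 and passed with sva (adjusted p = 0.0388), was -0.033 without both set-apart libraries and ranged from -0.045 (block, without replicate 2) to 0.95 when libraries were left out. The cause of these moves was not tested. For all siPGR libraries, the count of 3583 became 6289 with sva, 6319 without the 2 libraries and 6035 with them as a factor, and ranged from 1349 (block, without replicate 1) to 5065. For siPGR-1, 4817 became 8901, 9984 and 9166, and 8414 with the factor and the block, with a range of 2725 to 11655. For siPGR-2, 2750 became 6692, 7784 and 6986, and 6716 with the factor and the block, 1503 with only the 6 libraries compared and 5343 with the block added, with a range of 1011 to 9844. For siPGR-2 against siPGR-1, 753 became 1261 with the replicate block, 491 with library size only, 1561 with DESeq2, 1507 with DESeq2 and the block, 1658 with limma-voom, 4522 with sva, 6349 without the 2 libraries, 5273 with them as a factor, 3976 with the factor and the block, and 0 with only the 6 libraries and the block (edgeR, 3127 at an unadjusted p under 0.05), with a range of 13 (without siPGR-1 replicate 1) to 9033 (block, without replicate 2). The replicate block gave 3904, 5896 and 3452 genes for siPGR, siPGR-1 and siPGR-2 against siCtrl. Among the lists, 13 passed camera in the siPGR comparison, 1 with an estimated correlation and 0 with the block and an estimated correlation (5 at an unadjusted p under 0.05), with 13 to 15 when a library was left out. Between the siRNAs 14 passed, 4 with an estimated correlation, 3 with the block added (contractile, TGF-beta and growth factor lists), 8 with fry and 8 with fry and the block, with 13 to 15 when a library was left out. The correlation of both siRNAs' fold changes was 0.545 with controls of different numbers, 0.873 for genes with a mean of at least 50 counts and 0.740 without the 2 libraries. Over all named genes, 3510 values in other settings stayed on the same side of the threshold (among them values of ACTA2, CSRP1, ACTG2, TPM2 and NOTCH3, which had no call to keep under siPGR), 359 lost the call and 22 gained one, and for lists 364 kept and 68 lost it. Of 104 named genes called in the siPGR comparison, 92 kept the call in all 9 fits without 1 library. The block ended the call of FDFT1 (adjusted p = 0.0504) and gave NOTCH3 and the pericyte list one, as it did the retinoid list for siPGR-2 against siCtrl (camera adjusted p = 0.0596, and 0.0427 with the block, but adjusted p = 0.375 with the block and an estimated correlation). It changed no other call of named genes or of camera with the preset correlation. Other planned settings ended the siPGR call of SLCO2B1 (limma-voom), of FDFT1 and UQCRC2 (library size only, or no filter), the siPGR-1 calls of CCNG1 and TGM2 (library size only, no filter and others), and the siPGR-2 calls of MYOCD (only the 6 libraries compared) and TGM2 (no filter, or only the 6 libraries). Between the siRNAs they ended those of KIAA1199, THBS1, GREM1, CDC6, IDI1, DHCR7 and IGFBP3 (library size only), of IDI1 and IRF7 (no filter), of KIAA1199, THBS1, DHCR7 and IGFBP3 (mean of at least 50 counts), of KIAA1199, THBS1 and CDC6 (only the 6 libraries), of KIAA1199 (DESeq2 size factors) and of all 39 named (only the 6 libraries, with the block). The simulations changed only genes expected at over 50 counts, in independent libraries. At this depth and number of libraries they recovered 31.3% of genes changed 1.5-fold for siPGR and 7.46 to 13.4% in the other comparisons. Depth was not varied by itself.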

Other observations

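The tests of scaling, of other cells and of the 2 libraries for the division genes were chosen after the result was seen, and the counts of other splits were fixed before it. Genes of the siRNA machinery changed under siPGR although the list did not move as a whole. Of 13 tested, 3 were higher, 2 lower and 8 not passing, with equal counts adjusted over the list alone. DICER1, the nuclease that makes small RNAs, was 1.80-fold higher (log2 0.85, SE 0.09, edgeR adjusted p = 8.81e-05, 6 of 6 libraries) and its partner PRKRA 1.88-fold lower (log2 -0.91, SE 0.10), while DROSHA was 1.37-fold and TNRC6C 1.48-fold higher. DROSHA lost its call without siCtrl replicate 3 (adjusted p = 0.0638) and TNRC6C without any siCtrl or any siPGR-1 library (highest adjusted p = 0.0958). The median was -0.03 and camera's direction was up (adjusted p = 0.870). Of 25 p53 targets, 5 were higher and 7 lower (6 and 7 adjusted over the list alone, camera adjusted p = 0.745, median 0.05, mean -0.07), with TP53I3 2.86-fold and the antiproliferative BTG2 1.83-fold lower, SESN1 1.36-fold lower (call lost without siCtrl replicate 1, adjusted p = 0.0577) and MDM2, the p53 ubiquitin ligase, 1.32-fold higher. Of 36 interferon-stimulated genes, 4 were higher and 3 lower, with equal counts adjusted over the list alone (7 and 4 without siCtrl replicate 2 and siPGR-2 replicate 2, camera adjusted p = 0.997). Without these 2 libraries, 19 were higher and 4 lower with siPGR-1, against 7 higher and 11 lower with siPGR-2. Camera then gave an adjusted p = 0.0033 for siPGR-1, and 0.194 with an estimated correlation. SAMD9L and SAMD9 rose 2.16-fold and 1.97-fold, and ISG20 and IFITM1 fell 4.20-fold and 2.37-fold.

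Of 28 genes of the unfolded protein and amino acid stress response, 7 fell and 5 rose (8 and 5 adjusted over the list alone, 12 and 6 without siCtrl replicate 2 and siPGR-2 replicate 2, camera adjusted p = 0.201). The chaperone DNAJB9 fell 2.78-fold, SLC7A5 2.19-fold, CRELD2 1.82-fold and PDIA4 1.65-fold. Of 25 cholesterol genes 2 fell, DHCR7 2.34-fold and FDFT1 1.30-fold, and 1 adjusted over the list alone (8 lower and 1 higher without siCtrl replicate 2 and siPGR-2 replicate 2, camera adjusted p = 0.186). DHCR7 lost its call without siCtrl replicate 2 (adjusted p = 0.0672) and FDFT1 in 8 of 9 fits without 1 library, all but siPGR-2 replicate 2 (highest adjusted p = 0.143), and had an adjusted p = 0.0504 with the replicate block. In the BCL2 family BCL2L11, which promotes apoptosis, fell 1.42-fold, 1 of 15 also adjusted over the list alone, and lost its call without siCtrl replicate 1 (adjusted p = 0.0548), with a camera adjusted p = 0.614. Of 32 oxidative phosphorylation genes UQCRC2 fell 1.24-fold, and 0 passed adjusted over the list alone (2 at an unadjusted p under 0.05, 1 lower by DESeq2 and by limma-voom, 12 lower without siCtrl replicate 2 and siPGR-2 replicate 2, camera adjusted p = 0.793). That call was lost without siCtrl replicate 1, siCtrl replicate 3 or any siPGR-1 library (highest adjusted p = 0.146). edgeR called 0 of 34 ribosomal protein genes, with 0 at an unadjusted p under 0.05, 0 adjusted over the list alone and 0 by DESeq2 or limma-voom, but 5 lower without siCtrl replicate 2 and siPGR-2 replicate 2 (camera adjusted p = 0.745), and no mitochondrial gene had a count to test.

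For the rise of S phase and mitosis genes under siPGR the design names loss of PGR as a biological explanation, which was not tested apart from the groups themselves, and 3 technical explanations were tested. The mitosis median was at least 1.53 with each of 3 scalings (up to 1.64). Fewer cells of other types would raise genes of the main cell type, and 7 of 12 endothelial (median -0.54) and 3 of 10 pericyte markers (median -0.61) were lower. The contractile median, taken as a gauge of the main cell type, was -0.26 (quartiles -0.48 and -0.01), at -0.52 with siPGR-1 and -0.06 with siPGR-2. This list changed with the siRNAs themselves, since 16 of 29 genes fell with siPGR-1, while with siPGR-2 2 rose and 0 fell. Its median therefore cannot decide for or against fewer other cells. Without siCtrl replicate 2 and siPGR-2 replicate 2, 30 of 30 mitosis genes passed in the same direction, while a part played by other cells and off-target effects of each siRNA remain open.

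Other splits of the libraries were fitted in the same way. Of 84 splits of the 9 libraries into 3 and 6, 1, the real one, gave as many as 3583 genes. Every other split puts siCtrl and siPGR libraries into 1 group, which can widen the spread and lower the count. The share of 1 in 84 is also the smallest possible, so chance is not excluded. The highest other value was 907, with the 3 siPGR-1 libraries as the control, and that split is also the highest of the others among the 27 that take 1 library of each replicate number. The next was 360, with the 3 libraries of number 3 as the control, and the other 81 splits gave 0. With the replicate block, 1 of 27 such splits reached 3904, the real one, against a highest other value of 700, with the same limits. For siPGR-1 (4817), siPGR-2 (2750) and siPGR-2 against siPGR-1 (753), 10 splits each are too few for a share under 0.05, and the highest other split gave 0 in each.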
